A study of Mus musculus with 7 samples.

How the data were processed

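The deposited files hold, for each of 7 samples, a matrix of UMI counts per gene and cell barcode with its gene and barcode lists, 3 files per sample and 55357 features. The values are unnormalised counts per the file headers: whole numbers written by Cell Ranger, which keeps the barcodes it calls as cells. The submitters' processing notes name bcl2fastq 5.0.1 and Cell Ranger 7.0.0, and the labels name 10x 3′ v3.1 libraries. The genome build and annotation are not given in the sources used here, so no coordinates are printed. Samples were grouped by the labels as 3 controls and 4 treated with the IL-2/CD25 plasmid, and the labels give the same batch to all. The labels do not state which part of the liver was taken or whether immune cells were enriched, and they call the tissue of all 7 samples HCC tissue.

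Barcodes were kept with at least 500 UMIs, at least 200 genes and under 20% mitochondrial UMIs. Doublets were called in each sample by comparing cells with sums of random pairs of cells, and 5.81 to 8.51% of passing barcodes with the highest scores were removed. Cells were clustered with the Leiden method (leidenalg 0.10.2) on 30 principal components of 2000 variable genes with 20 neighbours and resolution 0.7, with no batch integration (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0). T and NK cells were clustered again at resolution 2 on 1500 genes, leaving out 6137 genes that other cells held at 5 times the level or more, and mixed dendritic and dividing clusters were clustered again on 1000 genes. This gave 59 clusters. A class name stands for cells that resemble that type by a list of marker genes, for example Ncr1 and Klrb1c for NK cells and ILC1, Cd8a and Cd8b1 for CD8 T cells, and Csf3r and S100a8 for neutrophils. In all, 8 clusters with 564 control and 1520 treated cells stayed unnamed because they were shallow, mixed or without a fixed marker list, and they made up 2.42% ± 0.507 of control and 4.45% ± 0.351 of treated cells. The authors deposited no cell annotation.

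Cells are not replicates, so all tests used the sample. Shares were compared by an exact two-sided permutation test of the difference between group means over 35 splits, with Benjamini-Hochberg adjustment (statsmodels 0.14.6). Raw UMI counts were summed per sample and class, in samples with at least 20 cells, and tested for 8 classes with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) with TMM scaling, the filterByExpr filter and Benjamini-Hochberg adjustment within the class, at an adjusted p of 0.05. Endothelial cells were not tested, since the controls held 34 in all. In addition 22 gene lists were tested in the classes with camera (limma 3.58.1, correlation 0.01) on log2 CPM, with adjustment over 152 tests, and again with an estimated correlation and with fry. These classes, tests, lists, filters and the rule for named genes were chosen before the data were examined. The rule took, per class and direction, up to 10 genes (15 for CD8 T cells and for hepatocytes and tumour cells) past the threshold with a mean of at least 20 CPM and no overlap between groups, ordered by fold change. Mitochondrial, ribosomal and unnamed gene models, immunoglobulin genes outside B cells and genes over 20 times higher in hepatocytes, B cells, neutrophils or erythroid cells were not named. Members of the lists were named as examples of their list. CPM means and SDs are over samples, and log2 changes are those fitted by edgeR. A gene with no UMI in a group was set against a floor of 3 counts over that group, and intervals and floors of this kind cover counting error only.

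Free RNA was estimated as the share of UMIs of a class that markers of other cell types would need if free RNA had the make-up of all UMIs of the sample, taking the median over marker lists, and was subtracted in an alternative. Other alternatives were median-of-ratios scaling, DESeq2 1.42.0, no low-count filter, the replicate number as a block, doublets kept, stricter cells (500 genes, 10% mitochondrial UMIs), CD4 and CD8 T cells taken by UMIs of Cd4, Cd8a and Cd8b1, immune cells as the denominator, edgeR on cell counts, shallow clusters left out, libraries thinned to the same summed UMIs within a class (cells and UMIs per cell stayed unequal) and each sample left out in turn. On simulated data made from these counts the edgeR test found, of genes changed 2-fold, 65.7% in CD8 T cells, 17.9% in CD4 T cells, 44.8% in NK cells and ILC1, 76.1% in monocytes and macrophages and 10.4% in hepatocytes and tumour cells. Camera called the raised list in all 5 and 0 of 20 unchanged lists in each. The simulated genes were drawn independently of each other, so this does not check camera on correlated genes. Figures were drawn with matplotlib 3.10.9.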

Results

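Liver cells from 7 mouse samples were profiled by droplet 3′ single-cell RNA sequencing 2 weeks after hydrodynamic tail vein injection, a rapid high-volume injection that carries plasmids into hepatocytes. All samples received plasmids for Nras and c-Myc, oncogenes that together drive liver tumours. The 4 treated samples also received a plasmid for IL-2/CD25, which joins the T cell growth factor interleukin 2 to the alpha chain of its receptor, and the 3 control samples did not. The controls held 9603, 7390 and 8759 cell barcodes with 98655145, 76438139 and 181755269 UMIs in total. The treated samples held 7263, 8838, 10637 and 10440 barcodes with 38492384, 37653600, 41729453 and 47881379 UMIs. After filters and removal of called doublets, 57739 cells remained, with a median of 5763 to 8410.5 UMIs per cell in the controls and 3107 to 4381 in the treated samples. The labels do not say whether the samples come from separate animals, so each p-value measures the spread between samples.

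The first comparison asked how the cell make-up of the liver differed with the IL-2/CD25 plasmid. NK cells and ILC1, cytotoxic and cytokine-making innate lymphocytes, were 2.29% ± 1.07 (SD, n = 3) of kept cells in the controls and 41.3% ± 4.60 (SD, n = 4) in the treated samples, an 18.04-fold higher share. All T cells together rose from 3.54% ± 1.07 to 28.7% ± 2.37. Within them, CD8 T cells, which kill infected and tumour cells, rose from 1.73% ± 0.966 to 6.42% ± 0.620, and CD4 T cells with regulatory cells included rose from 0.508% ± 0.017 to 4.25% ± 0.365. Regulatory T cells, suppressive cells marked by Foxp3 and Il2ra, rose from 0.249% ± 0.119 to 2.70% ± 0.823. Other T cells, among them clusters led by Zbtb16 or Klra6, rose from 1.30% ± 0.187 to 18.1% ± 1.91. CD8 T cells fell from 45.8% ± 16.1 to 22.3% ± 0.322 of all T cells.

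Monocytes, macrophages and neutrophils and the joint class of hepatocytes and tumour cells moved the other way. Monocytes and macrophages fell from 34.4% ± 7.69 of kept cells (SD, n = 3) to 1.52% ± 0.274 (SD, n = 4), a 22.6-fold lower share, while neutrophils fell from 31.1% ± 4.63 to 4.52% ± 0.730. The cDC1, dendritic cells that present antigen to CD8 T cells, fell from 3.28% ± 0.211 to 0.746% ± 0.096, and basophils or mast cells fell from 0.293% ± 0.082 to 0.10% ± 0.062. The joint class of hepatocytes and tumour cells fell from 13.7% ± 10.7 to 0.897% ± 0.648. Plasmacytoid dendritic cells, a source of type I interferon, rose from 1.15% ± 0.252 to 2.79% ± 0.642. Each difference named so far was seen in every treated sample against every control, with an exact two-sided permutation p of 0.0286, the smallest that 35 splits of the samples can give, and a Benjamini-Hochberg adjusted p of 0.044 over 20 tests. The exact permutation test did not call B cells (2.47% ± 1.12 against 11.1% ± 5.37, adjusted p = 0.114) or cDC2 (3.47% ± 0.948 against 2.12% ± 0.308, adjusted p = 0.0816). Nor did it call mature dendritic cells (adjusted p = 0.179), plasma cells (adjusted p = 0.301), endothelial cells (adjusted p = 0.286), cholangiocytes (adjusted p = 0.202) or regulatory cells among CD4 T cells (adjusted p = 0.40). For B cells every treated sample still lay above every control (6.29 to 16.4% against 1.29 to 3.51%). Cholangiocytes were at 0% in every control and at 0.021 to 0.704% in the treated samples. Shares of 1 sample add up to a whole, and control cells were sequenced deeper than treated cells. With immune cells as the denominator, or with shallow clusters left out, the exact permutation test no longer called plasmacytoid dendritic cells (adjusted p = 0.0714 in both) and did call cDC2 (adjusted p = 0.039 and 0.044). With CD8 and CD4 T cells taken by UMIs of their markers, the fall of CD8 among T cells was not called by the exact permutation test (adjusted p = 0.152), and edgeR on cell counts did not call basophils or mast cells (adjusted p = 0.0631). Of the control neutrophils 67.0% lay in cluster 2, a shallow cluster, and with shallow clusters left out the difference for neutrophils was -9.15 instead of -26.6 points of percent, still called. Without control 3 the difference for hepatocytes and tumour cells was -6.65 instead of -12.8 points. The clusters of this class moved in opposite directions. Cluster 5, which is tumour-like, fell from 13.7% ± 10.7 to 0.052% ± 0.045 of kept cells. Cluster 34, led by hepatocyte markers, rose from 0.030% ± 0.016 to 0.845% ± 0.665. Shares of single clusters were not tested. The fall of the class lay in cluster 5 and does not show a fall of hepatocytes. Nor does cluster 34 show a rise of them. Its cells had a median of 1617 UMIs and 0.1% mitochondrial UMIs, against 1.53% in cluster 5. Ptprc, a gene of immune cells, was found in 18.5% of them. Whether these barcodes are intact hepatocytes was not tested.

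**Figure D1:**
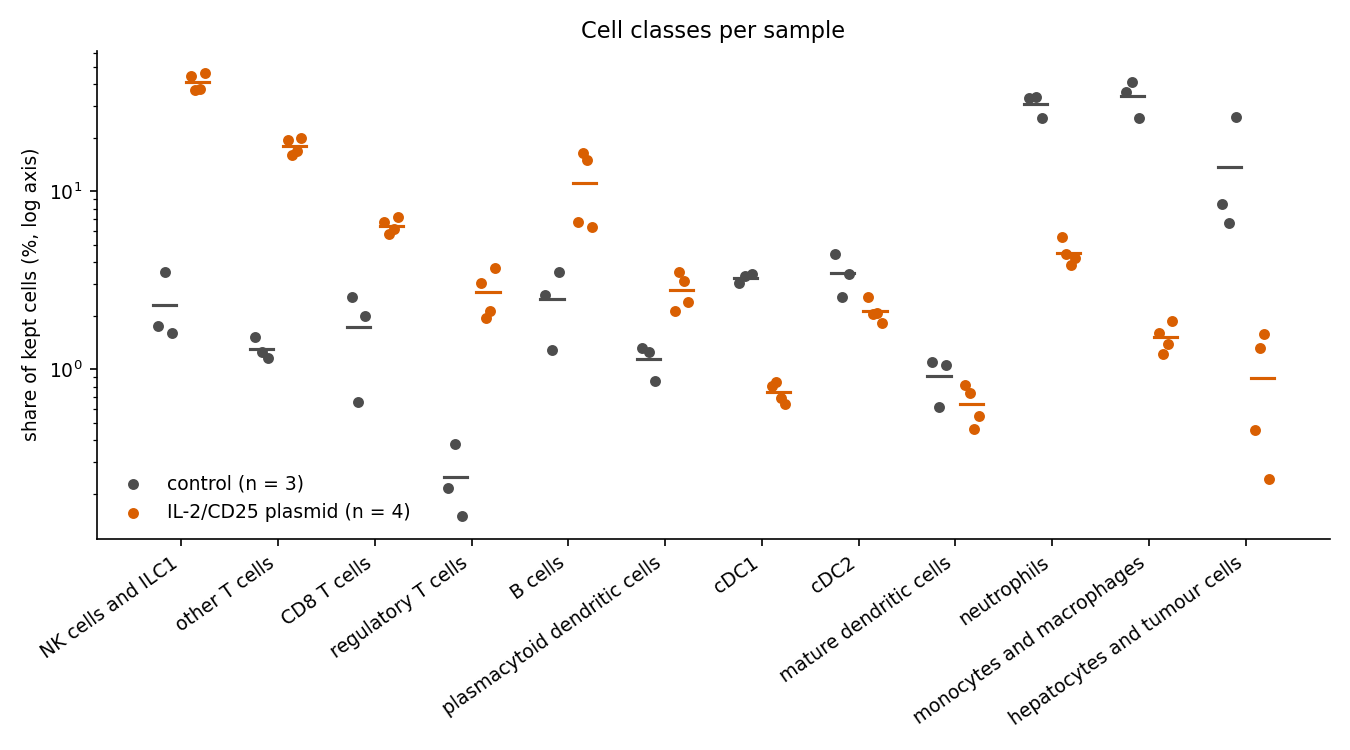
Share of kept cells per sample for 12 cell classes, on a log axis in percent, with 1 point per sample and a line at the group mean. Treated samples lie above all controls for NK cells and ILC1 and for CD8, regulatory and other T cells, and below all controls for neutrophils and for monocytes and macrophages.

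Counts of the genes carried by the plasmids show where their RNA was found. Nras (ENSMUSG00000027852), a small GTPase of the RAS pathway, had 3245 ± 42.7 CPM (SD, n = 3) in hepatocytes and tumour cells of the controls and 343 ± 197 CPM (SD, n = 4) in the treated samples, a log2 change of -3.28 (edgeR adjusted p = 0.000692). Myc (ENSMUSG00000022346), a growth-promoting transcription factor, had 2327 ± 190 CPM and 90.6 ± 86.6 CPM, a log2 change of -4.70 (edgeR adjusted p = 0.000196). In the controls this class held 94.9% of all Nras UMIs and 95.4% of all Myc UMIs. Cluster 5, which held most control cells of this class, was named in part by Myc among its leading genes. The place of Myc and its difference in this class are therefore not independent of the naming. Il2 (ENSMUSG00000027720) had 173 UMIs in all control cells and 481 in all treated cells, and its mean over all cells was 0.564 ± 0.105 CPM against 3.34 ± 0.142 CPM. Of the control Il2 UMIs, 69 (39.88%) lay in hepatocytes and tumour cells, against 5 of the treated ones. The mean of Il2 in this class was 0.36 ± 0.056 CPM in the controls and 2.338 ± 3.104 CPM in the treated samples. The treated mean rests on 5 UMIs of 312 cells, so neither a rise nor a fall of Il2 there is shown. Of the treated Il2 UMIs, 49.5% lay in other T cells and 40.8% in NK cells and ILC1. Within these classes the means lay closer, at 8.63 ± 6.30 against 9.63 ± 1.02 CPM in other T cells and 2.02 ± 1.40 against 3.70 ± 0.704 CPM in NK cells and ILC1. Il2ra (ENSMUSG00000026770), the gene for CD25, had 2.57 ± 1.34 CPM over all control cells and 57.2 ± 12.3 CPM over all treated cells, and regulatory T cells held 56.7% of the treated UMIs. Within classes Il2ra was higher in regulatory T cells (319.5 ± 101 against 977 ± 151 CPM), alike in other T cells (87.2 ± 20.95 against 84.6 ± 8.35 CPM) and lower in NK cells and ILC1 (29.4 ± 4.12 against 8.98 ± 0.165 CPM) and CD8 T cells (21.6 ± 0.798 against 7.75 ± 6.24 CPM). The control value in regulatory T cells rests on 65 UMIs of 57 cells, with 19, 26 and 12 cells in controls 1, 2 and 3. Il2ra was among the genes that named regulatory T cells, so its place and its difference there are not independent of the naming. This difference was not tested in regulatory T cells alone. In hepatocytes and tumour cells Il2ra had 0.184 ± 0.073 against 14.4 ± 12.05 CPM, from 25 and 17 UMIs. Since free RNA needed 7.40 to 16.9% of the treated UMIs of this class and treated samples had 57.2 CPM over all cells, a rise of Il2ra in hepatocytes and tumour cells is not shown. Il2 and Il2ra were not tested over all cells. A 3′ tag cannot tell a plasmid transcript from the mouse gene, and a plasmid whose 3′ end is missing from the reference gives no counts.

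**Figure D2:**
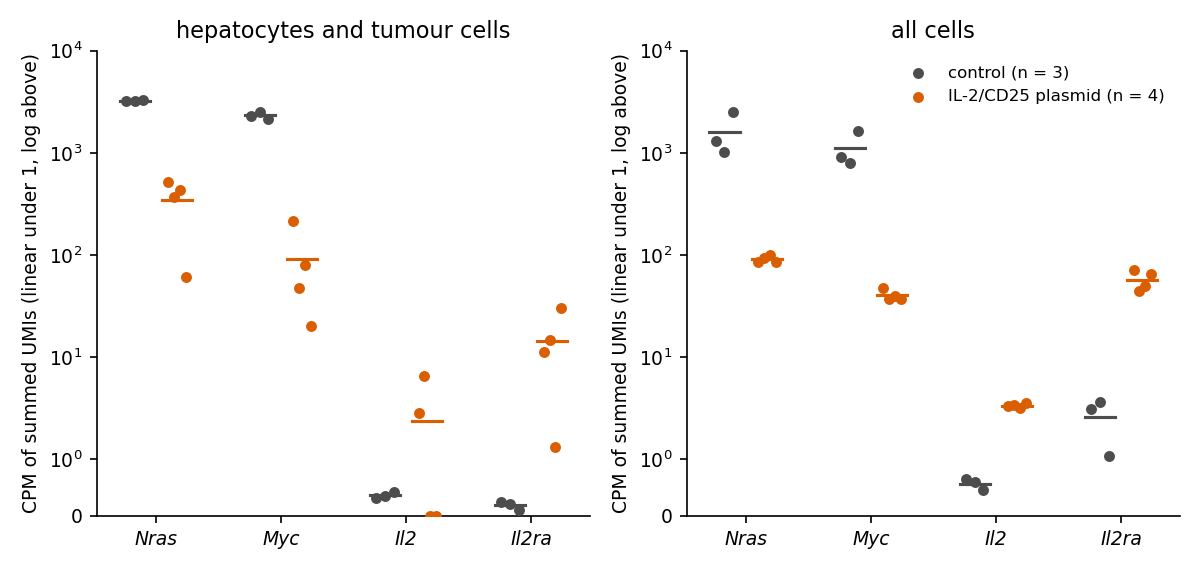
CPM of summed UMIs per sample for Nras, Myc, Il2 and Il2ra in hepatocytes and tumour cells and in all cells, on an axis that is linear under 1 and logarithmic above, with a line at the group mean. For Nras and Myc all treated samples lie below all controls in both panels.

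Hepatocytes and tumour cells differed in identity between the groups. In the controls 99.8% of them lay in cluster 5, led by Krt18, Cdkn2a and Myc, and in the treated samples 94.9% lay in cluster 34, led by Fabp1, Apoa2 and Ttr, with 16 treated cells in cluster 5. Of 7926 genes tested, 2159 were higher and 2002 lower in the treated samples (edgeR, adjusted p under 0.05). All 25 measured hepatocyte function genes rose (25 adjusted over the list alone), including Alb, the gene for albumin, from 20.9 ± 7.94 to 9096 ± 6635 CPM (SD, n = 3 and n = 4), and Cps1, the first enzyme of the urea cycle, with a log2 change of 10.93. The list was called by camera (adjusted p = 1.07e-17, and adjusted p = 0.348 with an estimated correlation). It shares Alb, Apoa1, Apoc3, Ttr, Trf, Fabp1 and Cps1 with the markers used to name this class, so its rise is not independent of the naming. Of 18 acute phase genes 17 rose (17 adjusted over the list alone), among them Hamp, the iron hormone hepcidin (log2 10.27), and Saa1 (log2 9.42). By camera they had adjusted p = 8.59e-09, and adjusted p = 0.402 with an estimated correlation. Car3, a carbonic anhydrase, had no UMI in the controls and was at least 135100-fold higher, against a floor of 3 counts over the group. Sult2a8, a sulfotransferase of bile acids, was at least 42660-fold higher on that floor. Lower genes included the bile duct keratins Krt19 (297 ± 20.9 to 6.00 ± 5.93 CPM) and Krt7 (log2 -5.22), and Prkg2, a cGMP-dependent kinase (log2 -6.12). All treated UMIs of Krt7 lay in treated sample 1. Of 27 proliferation genes 23 fell (24 adjusted over the list alone), for example Cdc20, an activator of mitotic exit (log2 -4.72). By camera they had adjusted p = 1.08e-05, and adjusted p = 0.425 with an estimated correlation. The genes that respond to MAPK signalling (2 higher and 2 lower of 13, camera adjusted p = 0.384) and the foetal liver and tumour genes (2 higher and 4 lower of 16, camera adjusted p = 0.119, adjusted p = 0.775 with an estimated correlation) were not called. In thinned libraries of hepatocytes and tumour cells camera called the foetal liver and tumour list lower (12 genes, adjusted p = 0.00327), a setting not run with an estimated correlation. The median control cell of this class held 35204 UMIs and the median treated cell 1621.5, and free RNA needed 8.90 to 14.2% of control and 7.40 to 16.9% of treated UMIs. The count of changed genes was 755 with libraries thinned to equal summed UMIs, 6433 without a low-count filter, 7145 by DESeq2 and 6301 without treated sample 1.

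CD8 T cells carried more transcripts of quiescent, recirculating cells and fewer of activated ones in the treated samples. Control CD8 T cells lay in cluster 28 (94.9%), and treated ones in clusters 11 (73.2%) and 27 (25.4%). Of 10533 genes tested, 3041 were higher and 3168 lower (edgeR, adjusted p under 0.05). Of 15 naive and memory T cell genes 13 rose (13 adjusted over the list alone). Satb1, a chromatin organiser, went from 86.0 ± 53.5 to 1286 ± 77.7 CPM (SD, n = 3 and n = 4). Ccr7, a chemokine receptor for entry into lymph nodes, and Il7r, the survival receptor for interleukin 7, rose by log2 3.23 and 2.59. The camera test gave this list adjusted p = 1.67e-05, and adjusted p = 0.402 with an estimated correlation. Of 22 cytotoxic effector genes 11 fell and 0 rose (11 and 0 adjusted over the list alone). Gzmk, a granule protease, went from 229.8 ± 43.4 to 3.32 ± 1.51 CPM, and Gzmb, another, changed by log2 -3.95. Prf1, the gene for perforin, had 72.8 ± 31.1 against 94.5 ± 8.58 CPM (edgeR adjusted p = 0.26). Of 16 inhibitory receptor and exhaustion genes 12 fell and 1 rose (12 and 2 adjusted over the list alone). Pdcd1, the gene for PD-1, went from 80.5 ± 28.6 to 2.60 ± 2.38 CPM, and the checkpoint receptors Lag3 and Havcr2 changed by log2 -3.70 and -2.77. Camera gave the cytotoxic list adjusted p = 0.0308 (adjusted p = 0.605 with an estimated correlation) and the exhaustion list adjusted p = 0.0118 (adjusted p = 0.402 with an estimated correlation). All 30 proliferation genes fell (30 adjusted over the list alone), including Mki67 (609.8 ± 233.6 to 49.1 ± 19.4 CPM) and Birc5, a mitotic survival factor (log2 -4.51). By camera this list had adjusted p = 3.84e-13, and adjusted p = 0.348 with an estimated correlation. The IL-2/STAT5 response genes went both ways, 8 higher and 6 lower of 23 (8 and 6 adjusted over the list alone; camera adjusted p = 0.772). Socs3, an inhibitor of cytokine signalling, and the kinase Pim2 rose by log2 2.27 and 2.18. Cish, an inhibitor of STAT5 signalling, and Il2ra changed by log2 -2.78 and -1.53. The camera call of the cytotoxic list was lost without control 1 (adjusted p = 0.07), without treated sample 2 (adjusted p = 0.0535), with doublets kept (adjusted p = 0.0732) and with CD8 T cells taken by UMIs (adjusted p = 0.504). The camera call of the exhaustion list was lost by UMIs (adjusted p = 0.168) and in thinned libraries (adjusted p = 0.0792). Free RNA needed 11.4 to 13.4% of control and 5.49 to 12.7% of treated UMIs, and with libraries thinned to equal summed UMIs 3651 genes were called.

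CD4 T cells, regulatory cells included, lay in clusters 20 and 25 in both groups, with 47.5% and 52.5% of the control cells and 63.0% and 37.0% of the treated cells. Of 9810 genes tested, 141 were higher and 151 lower in the treated samples (edgeR, adjusted p under 0.05). Klrg1, a receptor of differentiated lymphocytes, went from 38.6 ± 14.3 to 406 ± 87.3 CPM (SD, n = 3 and n = 4). Rgs16, a regulator of chemokine receptor signalling, went from 2.64 ± 4.58 to 87.1 ± 15.3 CPM, and Nr4a3, an activation-induced nuclear receptor, from 19.6 ± 8.29 to 109 ± 22.04 CPM. Ifit1, an interferon-induced RNA-binding protein, fell from 113 ± 61.9 to 11.7 ± 2.51 CPM. The unnamed cluster 41, T and NK cells led by interferon genes, is not part of this class. Of 23 IL-2/STAT5 response genes 4 rose and 0 fell (10 and 2 adjusted over the list alone). Those that rose were Icos, a costimulatory receptor (log2 2.34), Il2ra (log2 1.97), Dusp5, a MAPK phosphatase (log2 1.90), and Pim1, a survival kinase (log2 1.41). For this list camera gave adjusted p = 0.015, and adjusted p = 0.47 with an estimated correlation. Of 13 genes of the regulatory T cell programme 3 rose and 0 fell (5 and 1 adjusted over the list alone). These were Lrrc32, which holds latent TGF-beta at the surface (log2 1.95), the folate receptor Izumo1r (log2 1.79) and the TNF receptor Tnfrsf1b (log2 1.63). Foxp3, the master factor of these cells, had 216 ± 105 against 419 ± 119 CPM (edgeR adjusted p = 0.138). The regulatory T cell list had camera adjusted p = 0.015, and adjusted p = 0.472 with an estimated correlation. The camera call of the IL-2/STAT5 list was lost without control 3 (adjusted p = 0.0829), and that of the regulatory T cell list without control 1 (adjusted p = 0.07) and control 3 (adjusted p = 0.13). The controls held 120 CD4 T cells, and free RNA needed 10.8 to 18.3% of control and 16.6 to 21.3% of treated UMIs. The count of changed genes was 123, 174 and 153 without controls 1, 2 and 3, 164 with free RNA subtracted, 193 in thinned libraries, 444 by DESeq2, 670 without a low-count filter and 899 with cells taken by UMIs.

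NK cells and ILC1 gained transcripts of mature killer cells and lost those of dividing cells. Control cells lay mainly in cluster 26 (91.0%) and treated cells mainly in others, of which cluster 3 (34.2%) and cluster 7 (16.04%) were the largest. Of 13569 genes tested, 2960 were higher and 2956 lower (edgeR, adjusted p under 0.05). Itga1, a collagen-binding integrin of liver ILC1, went from 10.4 ± 2.39 to 137 ± 18.6 CPM (SD, n = 3 and n = 4). Cma1, a chymase, went from 38.7 ± 1.28 to 314 ± 39.3 CPM, and S1pr5, a receptor that guides mature NK cells out of tissue, rose by log2 2.72. Of 23 cytotoxic effector genes 15 rose and 3 fell (15 and 3 adjusted over the list alone). Cx3cr1, the fractalkine receptor (log2 3.48), Klrg1 (log2 1.99), Prf1 (490.6 ± 28.2 to 1601 ± 29.2 CPM) and Gzmb (log2 1.31) rose, while Tnf, an inflammatory cytokine, fell (log2 -2.67). The camera test gave adjusted p = 0.00127, and adjusted p = 0.348 with an estimated correlation. All 30 proliferation genes fell (30 adjusted over the list alone), among them the mitotic genes Ube2c (log2 -6.63) and Birc5 (log2 -6.16). The camera test of this list gave adjusted p = 8.41e-14, and adjusted p = 0.363 with an estimated correlation. Of 12 MHC class II presentation genes 10 fell (10 adjusted over the list alone), for example Cd74, the invariant chain (370 ± 25.9 to 113 ± 24.2 CPM). By camera they had adjusted p = 4.66e-06, and adjusted p = 0.353 with an estimated correlation. Interferon response genes (4 higher and 15 lower of 35, camera adjusted p = 0.0814) and IL-2/STAT5 response genes (6 higher and 7 lower of 24, camera adjusted p = 0.587) were not called. Within cluster 26 alone, a test added after the data were seen, camera called the IL-2/STAT5 list higher (7 higher and 2 lower of 10, adjusted p = 0.0186, and 0.0434 with free RNA subtracted) and the interferon list lower (1 higher and 3 lower of 9, adjusted p = 0.0144, and 0.0467 with free RNA subtracted). With an estimated correlation these had adjusted p = 0.294 and 0.132 in cluster 26 as counted and 0.405 and 0.205 with free RNA subtracted. Cluster 26 held 0.81% of the treated cells of this class. Over all NK cells and ILC1 camera called the interferon list lower without a low-count filter (adjusted p = 0.00442), without control 1 (adjusted p = 0.0273) and without control 3 (adjusted p = 0.0442), and it had adjusted p = 0.65 with an estimated correlation. The unnamed cluster 41, led by interferon genes with T and NK cells mixed, was left out of this class. Free RNA needed 8.68 to 14.6% of control and 5.09 to 26.7% of treated UMIs, and in libraries thinned to equal summed UMIs 2670 genes were called. With free RNA subtracted 3 of 8 measured MHC class II genes fell and 0 rose in NK cells and ILC1, with a median log2 change of -3.355.

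**Figure D3:**
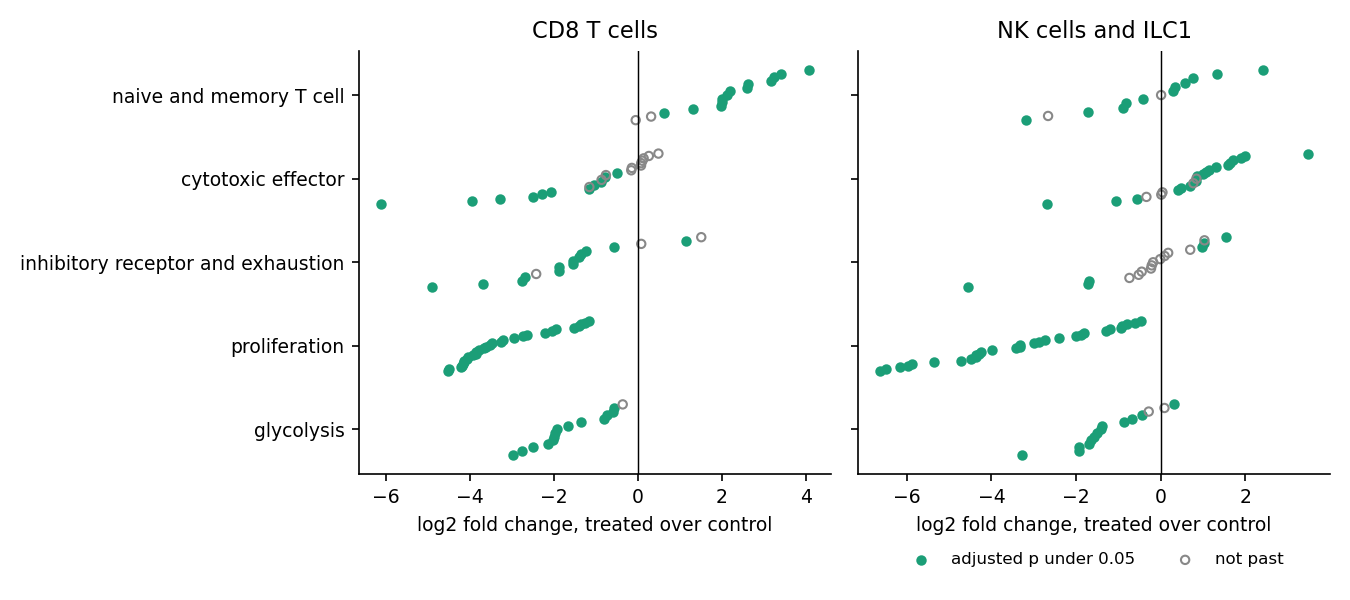
Log2 fold change, treated over control, of each measured gene of 5 lists in CD8 T cells and in NK cells and ILC1, with 1 point per gene, filled where the edgeR adjusted p is under 0.05. In CD8 T cells 13 of 15 naive and memory genes rose and 30 of 30 proliferation genes fell.

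B cells had 848 genes higher and 1191 lower of 9592 tested (edgeR, adjusted p under 0.05). Control B cells lay in cluster 24 (90.5%), a cluster with a median of 1772 UMIs per cell, and treated ones in cluster 4 (98.4%). Slamf1, a signalling receptor of lymphocytes, went from 10.8 ± 7.69 to 42.0 ± 4.88 CPM (SD, n = 3 and n = 4). Hdac9, a histone deacetylase, went from 9.96 ± 6.83 to 44.8 ± 5.51 CPM, and Gdf11, a TGF-beta family member, rose by log2 1.65. Of 13 naive and memory genes 8 rose and 2 fell (8 and 2 adjusted over the list alone). The follicle homing receptor Cxcr5, Ccr7 and the egress receptor S1pr1 rose by log2 1.34, 1.26 and 1.11, and Il7r fell by 3.50. Camera gave adjusted p = 0.015, and adjusted p = 0.383 with an estimated correlation. Of 19 immediate early and dissociation stress genes 7 fell and 1 rose (7 and 2 adjusted over the list alone), among them the heat shock gene Hspa1a (log2 -5.12) and Jun, a transcription factor of early activation (1161 ± 160 to 423 ± 63.3 CPM). By camera they had adjusted p = 0.015, and adjusted p = 0.472 with an estimated correlation. The naive list was not called by camera without control 1 (adjusted p = 0.0722) or with free RNA subtracted (adjusted p = 0.167), nor the stress list without control 2 (adjusted p = 0.0527). Free RNA needed 13.8 to 23.5% of control and 4.75 to 7.05% of treated UMIs, and the count of changed genes was 830 with it subtracted, 887 in thinned libraries and 1173 without control 3.

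Monocytes and macrophages of the treated samples carried transcripts of resident Kupffer cells and of the interferon response. Control cells lay in clusters 1 (72.1%) and 8 (23.9%), and treated cells in clusters 35 (55.9%) and 8 (31.0%). Of 9352 genes tested, 2589 were higher and 2578 lower (edgeR, adjusted p under 0.05). All 13 complement C1q and Kupffer cell genes rose (13 adjusted over the list alone). Clec4f, a lectin of Kupffer cells, went from 0.684 ± 0.505 to 84.7 ± 38.3 CPM (SD, n = 3 and n = 4). Vsig4, a complement receptor, Slc40a1, the iron exporter ferroportin, and C1qc, a subunit of complement C1q, rose by log2 5.88, 5.90 and 2.03. Camera gave adjusted p = 8.42e-07, and adjusted p = 0.348 with an estimated correlation. Of 36 interferon response genes 21 rose and 0 fell (22 and 0 adjusted over the list alone), including Cxcl9, a chemokine that draws T cells (log2 4.66), and Gbp5, a guanylate-binding protein (log2 2.71 ± 0.241 SE). By camera they had adjusted p = 7.55e-07, and adjusted p = 0.402 with an estimated correlation. Il1r2, a decoy receptor for interleukin 1, fell from 1107 ± 291 to 6.98 ± 4.31 CPM. Lcn2, an iron-scavenging lipocalin, fell from 1042 ± 284 to 33.5 ± 38.6 CPM, and Arg1, an arginine-degrading enzyme of suppressive macrophages, from 770 ± 66.4 to 36.9 ± 48.8 CPM. Rnase2a had no UMI in the treated samples and was at least 112-fold lower, against a floor of 3 counts over the group. Of 28 proliferation genes 20 fell (21 adjusted over the list alone), with camera adjusted p = 3.76e-05 and adjusted p = 0.472 with an estimated correlation. Free RNA needed 19 to 44.4% of control and 9.93 to 16.6% of treated UMIs, and 3377 genes were called in libraries thinned to equal summed UMIs. With free RNA subtracted 7 of 23 measured proliferation genes fell and 0 rose in monocytes and macrophages, with a median log2 change of -1.348.

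**Figure D4:**
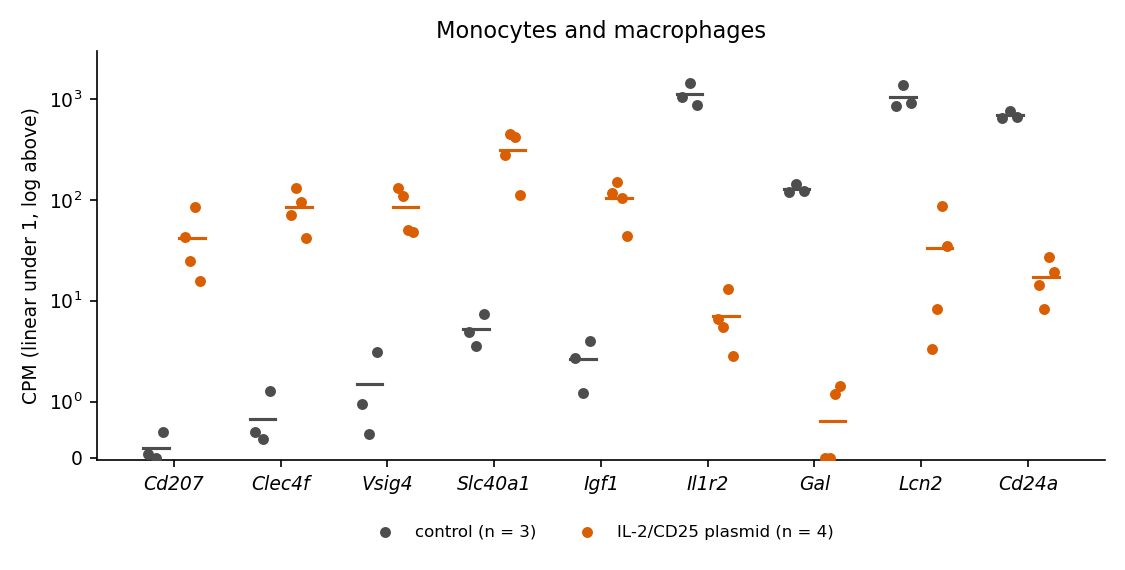
CPM per sample of 9 genes in monocytes and macrophages, on an axis that is linear under 1 and logarithmic above, with 1 point per sample and a line at the group mean. All treated samples lie above all controls for Cd207, Clec4f, Vsig4, Slc40a1 and Igf1, and below all controls for Il1r2, Gal, Lcn2 and Cd24a.

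Neutrophils had 1833 genes higher and 1945 lower of 7262 tested (edgeR, adjusted p under 0.05). Control neutrophils lay in clusters 2 (67.0%) and 6 (32.7%), and treated ones in cluster 14 (97.2%). Of 19 MHC class I presentation genes 16 rose and 1 fell (16 and 1 adjusted over the list alone). The class I molecules H2-Q6 (6.78 ± 3.27 to 90.1 ± 38.5 CPM, SD, n = 3 and n = 4) and H2-Q7 (log2 3.29) and their light chain B2m (677 ± 118 to 1811 ± 137 CPM) rose. Camera gave adjusted p = 6.55e-06, and adjusted p = 0.379 with an estimated correlation. Nr4a1 and Egr3, transcription factors of early activation, went from 52.9 ± 26.8 to 551 ± 46.1 CPM and from 18.3 ± 8.97 to 213 ± 30.1 CPM. Lipg, endothelial lipase, fell from 421 ± 24.2 to 3.45 ± 2.08 CPM. All 8 measured MHC class II genes fell (8 adjusted over the list alone; camera adjusted p = 0.0019, adjusted p = 0.45 with an estimated correlation), for example Cd74 from 358 ± 92.2 to 207 ± 35.3 CPM. Interferon response genes were not called by camera (14 higher and 6 lower of 30, adjusted p = 0.0771, and 0.764 with an estimated correlation). In neutrophils camera called them higher without a low-count filter (adjusted p = 0.00112), with shallow clusters left out (adjusted p = 0.0486) and without control 2 or treated sample 1, 3 or 4 (adjusted p = 0.00493, 0.00795, 0.0183 and 0.0281). Free RNA needed 16.9 to 17.6% of control and 4.49 to 7.68% of treated UMIs. With it subtracted the fall of the MHC class II genes was gone: of 4 left, too few for camera, 1 rose and 0 fell in neutrophils, with a median log2 change of 1.96.

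Dendritic cells (cDC1, cDC2 and mature cells) had 2954 genes higher and 3074 lower of 11290 tested (edgeR, adjusted p under 0.05). Control cells lay mainly in clusters 19 (42.1%) and 23 (40.9%), and treated ones in clusters 33 (28.8%), 19 (21.3%), 29 (18.03%) and 42 (14.97%). Of 14 inflammatory genes 9 rose and 0 fell (9 and 0 adjusted over the list alone). Il12b, a subunit of the T cell-activating cytokine interleukin 12, went from 11.3 ± 3.29 to 126 ± 34.8 CPM (SD, n = 3 and n = 4). Il1b, an inflammatory cytokine, went from 89.4 ± 24.2 to 765 ± 281 CPM, and Ptgs2, a prostaglandin synthase, rose by log2 2.84. The inflammatory list had camera adjusted p = 0.015, and adjusted p = 0.45 with an estimated correlation. Of 30 proliferation genes 29 fell and 1 rose (29 and 1 adjusted over the list alone), with camera adjusted p = 2.1e-07 and adjusted p = 0.402 with an estimated correlation. Birc5 went from 71.0 ± 9.41 to 35.5 ± 10.6 CPM. Tdgf1, a co-receptor of nodal signalling, and Mif, a macrophage cytokine, changed by log2 -6.05 and -2.88. In dendritic cells the inflammatory list was not called by camera without treated sample 1 (adjusted p = 0.0532), without treated sample 3 (adjusted p = 0.0569) or with free RNA subtracted (adjusted p = 0.123). Free RNA needed 13.98 to 14.6% of control and 15.5 to 18.5% of treated UMIs.

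Glycolysis genes, which encode the steps from glucose uptake to lactate export, were lower in the treated samples in most classes. Of 15 measured genes, 14 fell in CD8 T cells, 12 fell and 1 rose in NK cells and ILC1, 15 fell in monocytes and macrophages, 14 in neutrophils, 13 in dendritic cells and 15 in hepatocytes and tumour cells. Adjusted over the list alone, 15 fell in CD8 T cells, 13 in NK cells and ILC1, 15 in monocytes and macrophages, 14 in neutrophils, 13 in dendritic cells and 15 in hepatocytes and tumour cells. Ldha, lactate dehydrogenase, went from 889 ± 130 to 221 ± 16.6 CPM in CD8 T cells and from 1203 ± 118 to 259.5 ± 44.7 CPM in monocytes and macrophages, and Tpi1, triosephosphate isomerase, from 474.5 ± 59.3 to 49.8 ± 7.14 CPM in neutrophils. Hk2, which traps glucose in the cell, went from 20.4 ± 1.28 to 2.09 ± 0.606 CPM in NK cells and ILC1. Camera gave adjusted p between 1.79e-09 in monocytes and macrophages and 2.14e-05 in hepatocytes and tumour cells for these 6 classes, and with an estimated correlation adjusted p = 0.285 in neutrophils, 0.346 in dendritic cells and 0.348 in the other 4. In B cells 13 fell (14 adjusted over the list alone; camera adjusted p = 2.27e-10, adjusted p = 0.285 with an estimated correlation) and in CD4 T cells 1 fell (6 adjusted over the list alone; camera adjusted p = 0.00383, adjusted p = 0.472 with an estimated correlation). With free RNA subtracted camera called neither B cells (adjusted p = 0.398) nor CD4 T cells (adjusted p = 0.355).

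**Figure D5:**
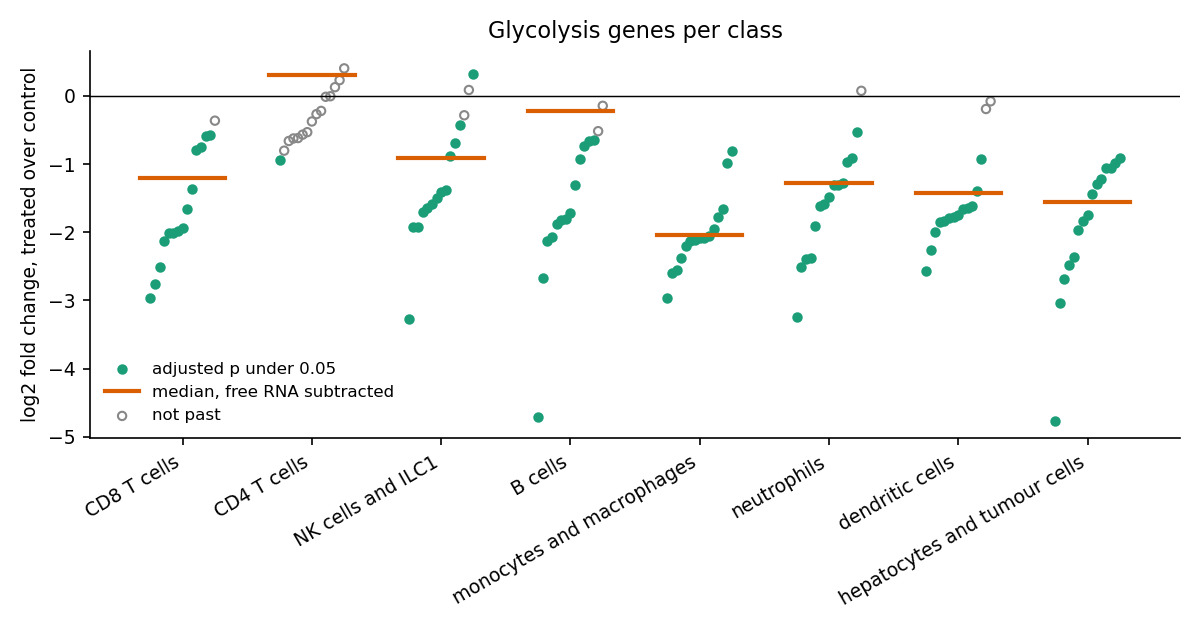
Log2 fold change, treated over control, of 15 glycolysis genes in 8 cell classes, with 1 point per gene, filled where the edgeR adjusted p is under 0.05, and a bar at the median with free RNA subtracted. The bar lies at 0.30 in CD4 T cells and -0.22 in B cells, and between -2.05 and -0.91 in the 6 remaining classes.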

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

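The search for single samples apart from the rest of their group was set before the values were seen, and covered 215 sets of values of the treated group, since the control group was too small for it. Chance puts about 1 in 20 groups apart, and 18 of 215 were: 9 in treated sample 4, 6 in treated sample 1, 3 in treated sample 2 and 0 in treated sample 3. None lay among the 22 shares of cells, the depths or the counts of plasmid genes. Shares of single clusters were not searched. Several clusters of NK cells and ILC1 had Gzma among their leading genes. Treated sample 4 was highest in cluster 12 (13.046% of kept cells, other treated samples 0.471 to 1.971%) and cluster 21 (8.382%, 0.272 to 1.099%). It was lowest in cluster 3 (6.933%, 11.93 to 19.202%) and between the others in cluster 7 (6.765%). It was also highest in cluster 32 of other T cells (2.479%, 0.105 to 0.208%). No explanation was tested for the values set apart or for these shares.

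Gzma, a granule protease of killer cells, was highest in treated sample 4 in each of 3 classes. It had 235 CPM in CD4 T cells (the other samples 108 to 121), 276 CPM in neutrophils (114 to 129) and 248.5 CPM in dendritic cells (92.4 to 113). In the same sample Il2rb, a receptor chain for interleukin 2, had 62.8 CPM in neutrophils (34.3 to 38.8), Gimap4, a lymphocyte GTPase, 54.3 CPM in dendritic cells (29.7 to 30.6), and Chil3, a myeloid lectin, 20.2 CPM in hepatocytes and tumour cells (0 to 2.76). Mir6236 was lowest there in B cells, at 421 CPM (772.5 to 839).

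Treated sample 1 stood apart for Cenpf, a kinetochore gene, in NK cells and ILC1 (4.85 CPM, the others 0.726 to 1.01), Ccl6, a myeloid chemokine, in B cells (18.7 CPM, the others 8.15 to 9.82) and Enah, an actin regulator, in dendritic cells (21.6 CPM, the others 9.59 to 10.3). In hepatocytes and tumour cells it was the only treated sample with UMIs of Krt7 (77.2 CPM) and of Vcan (5.51 CPM). Treated sample 2 had the lowest Ccr6, a chemokine receptor, in CD4 T cells (2.67 CPM, the others 7.36 to 7.56). Counts near the floor stood apart too: Dynap and Robo3 in hepatocytes and tumour cells (1.60 CPM each in treated sample 2, the others 0), Wfdc2 and Rab15 in neutrophils (0.938 CPM each in treated sample 4, the others 0) and F7 in neutrophils (0 CPM in treated sample 1, the others 0.938 to 1.01).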

How the results depend on the processing

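The subtraction of free RNA, the removal of shallow clusters, the thinning of libraries and the single clusters were chosen only after the data had been seen, and the cause of the changes listed was not tested. Of 180 named genes, 179 kept direction and call with median-of-ratios scaling, doublets kept and stricter cells, 178 without a low-count filter, 177 by DESeq2, 145 of 146 with free RNA subtracted, 45 of 50 with T cells taken by UMIs and 20 of 20 with shallow clusters left out, and 13 lost the call when some 1 sample was left out. Of 68 list calls, 67 stayed with median-of-ratios scaling, 66 with stricter cells, 65 without a low-count filter, 64 with doublets kept, 61 by fry, 51 of 61 in thinned libraries, 15 of 20 with T cells taken by UMIs and 26 of 59 with free RNA subtracted, and 17 were lost when some 1 sample was left out. With the replicate number as a block 172 of the genes and 64 of the lists kept their call, and the interferon list in neutrophils became called (adjusted p = 0.0431). The numbers do not pair samples: correlations between samples of the same number lay between -0.128 and 0.109, and in 5 of 24 combinations of class and control sample the treated sample of the same number correlated best. Of 5 classes simulated, CD4 T cells and hepatocytes and tumour cells had the lowest shares of genes changed 4-fold that were found, 57.6% and 69.7%, against 92.4% in CD8 T cells.

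Counts of changed genes moved by more than 1.5 times as follows. In thinned libraries 3651 were called in CD8 T cells, 193 in CD4 T cells, 2670 in NK cells and ILC1, 887 in B cells, 3377 in monocytes and macrophages and 755 in hepatocytes and tumour cells, where fewer UMIs and fewer genes were tested. With free RNA subtracted the counts were 164 in CD4 T cells, 830 in B cells, 791 in plasmacytoid dendritic cells, 829 in mature dendritic cells and 417 in T cells of cluster 17. DESeq2 called 444 in CD4 T cells and 7145 in hepatocytes and tumour cells, and without a low-count filter these were 670 and 6433. With T cells taken by UMIs 899 were called in CD4 T cells. Leaving out 1 sample gave 123 to 271 in CD4 T cells, lowest without control 1, 1173 to 1997 in B cells, lowest without control 3, and 3196 to 6301 in hepatocytes and tumour cells, highest without treated sample 1. Lists past the threshold were 34 with free RNA subtracted and 0 with an estimated correlation, where 19 had an unadjusted p under 0.05 and the lowest adjusted p was 0.285, against 93 by fry.

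Lists that turned direction are given with the camera adjusted p after the turn. With free RNA subtracted these were, in CD4 T cells, cytotoxic effector 0.933, alternative macrophage 0.236, neutrophil maturation 0.933, foetal liver and tumour 0.00386 and glycolysis 0.355. In NK cells and ILC1 they were alternative macrophage 0.291, foetal liver and tumour 0.344 and MAPK output 0.96, and in B cells neutrophil maturation 0.00133, foetal liver and tumour 0.0619 and glycolysis 0.398. In monocytes and macrophages foetal liver and tumour gave 0.96, in neutrophils cytotoxic effector 0.26, and in dendritic cells cytotoxic effector 0.903, alternative macrophage 0.962 and foetal liver and tumour 0.191. In thinned libraries interferon response in CD4 T cells (0.196) and MAPK output in NK cells and ILC1 (0.831) turned, and without a low-count filter MAPK output in CD4 T cells (0.791). Gzma in CD4 T cells turned to a log2 change of -0.022 with cells taken by UMIs.

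For shares, treated minus control in points of percent, cDC2 became called with immune cells as the denominator (-1.97), stricter cells (-1.58) and shallow clusters left out (-2.43), and plasmacytoid dendritic cells lost the call with immune cells as the denominator (1.52) and shallow clusters left out (1.34). CD8 among T cells lost it with cells taken by UMIs (-11.5). Called shares that moved by more than 1.5 times and stayed called were neutrophils (-26.6 to -9.15) and basophils or mast cells (-0.193 to -0.29) with shallow clusters left out, and CD8 T cells by UMIs (4.69 to 7.76). On cell counts edgeR gave log2 changes of 2.17 for B cells, -0.71 for cDC2 and 7.76 for cholangiocytes, all called, and -1.52 for basophils or mast cells, not called. With 1 sample left out the exact permutation test of shares cannot pass the threshold, so only the differences were compared, and none of the called shares changed direction, though hepatocytes and tumour cells went from -12.8 to -6.65 without control 3.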

Other observations

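The comparisons within single clusters, the thinning of libraries and the tests of free RNA, shallow clusters, tissue and dilution were chosen after the data were seen, and the splits of the samples were not. Clusters held in both groups allow a comparison that a change of clusters cannot make, though cells within a cluster can still differ in type. In plasmacytoid dendritic cells 634 genes were higher and 854 lower of 8993 tested (edgeR, adjusted p under 0.05). With free RNA subtracted 434 were higher and 357 lower of 8376. Socs2, an inhibitor of cytokine signalling, fell from 138.5 to 4.42 CPM and Fkbp5, a target of glucocorticoids, from 390 to 42.9 CPM. Of 12 MHC class II genes 5 rose and 0 fell (camera adjusted p = 0.00518, adjusted p = 0.2 with an estimated correlation). Of 24 interferon response genes 2 rose and 6 fell (camera adjusted p = 0.0151, adjusted p = 0.576 with an estimated correlation), and with free RNA subtracted 0 rose and 5 fell (camera adjusted p = 0.000159, adjusted p = 0.41 with an estimated correlation). In cDC1 1551 genes were higher and 1484 lower of 7996, with Egr3, an activation factor, at log2 3.12 and Tdgf1 at log2 -6.03. In mature dendritic cells 705 were higher and 818 lower of 5982, and with free RNA subtracted 448 were higher and 381 lower of 5012. As counted, Il12b there went from 118 to 832 CPM and Cxcl9 rose by log2 4.00, while Mif fell from 865.5 to 82.4 CPM. Of 19 MHC class I genes 11 rose and 2 fell there (camera adjusted p = 0.00016, adjusted p = 0.2 with an estimated correlation).

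In macrophages of cluster 8, led by C1qa, C1qb and C1qc, 1500 genes were higher and 1522 lower of 5839 tested (edgeR, adjusted p under 0.05). Clec4f rose by log2 6.77, and all 13 complement C1q and Kupffer cell genes rose (camera adjusted p = 5.15e-09, adjusted p = 0.111 with an estimated correlation). Egln3 and Ndrg1, genes induced by low oxygen, changed by log2 -6.04 and -4.92. Of 22 interferon response genes 15 rose and 0 fell (camera adjusted p = 0.000248, adjusted p = 0.403 with an estimated correlation). T cells of cluster 17, led by Ikzf2 and Klra6, had 370 genes higher and 520 lower of 8164. S1pr1, an egress receptor, went from 113 to 410 CPM there, and the interferon-induced genes Cxcl10 and Ifit1 fell from 447 to 8.27 CPM and from 134 to 8.13 CPM. Of 23 interferon response genes in these T cells 5 fell and 0 rose (camera adjusted p = 0.0431, adjusted p = 0.452 with an estimated correlation). Cluster 41, unnamed and led by interferon genes with T and NK cells mixed, held 0.095% of control and 0.475% of treated kept cells. T and NK cells with the most interferon transcripts were thus set apart by the clustering before interferon genes were compared within T and NK cells. Whether the change of the interferon genes differs between clusters was not tested.

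Macrophage, neutrophil and tumour genes were lower in treated lymphocytes: all 12 such lists in CD8 T cells, CD4 T cells, NK cells and ILC1 and B cells were called lower by camera, and 0 with an estimated correlation (lowest adjusted p 0.285). Free RNA of the controls, which held many myeloid and tumour cells, may account for most of this. For 90 members called lower, the median log2 ratio of control UMIs to those that free RNA would give was -0.138 (quartiles -0.455 and 0.224), with 12 members over 2 times the free RNA level, and 0 of 10 lists that could be tested were called lower after subtraction. The amount subtracted was set by markers of other cell types, and some of these markers are members of the lists. Subtraction removes such RNA whatever its source, so the loss of the calls is partly built in. Unequal summed UMIs do not account for the lower lists as a whole, since 10 of the 12 calls stayed in libraries thinned to equal summed UMIs. Thinning left UMIs per cell unequal, so it could not test deeper sequencing of the control cells. Real uptake of myeloid RNA by lymphocytes was not tested.

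Lymphocyte shares rose while monocytes, macrophages and neutrophils fell, in 7 called classes. A pure gain of lymphocytes would thin out every other class alike, but the log2 ratio of monocytes and macrophages to cDC2 differed by -3.81 between groups (2.91 to 4.01 in the controls, -0.74 to 0.03 in the treated samples), which argues against it as the whole cause. Shallow clusters do not account for it as a whole, as all 7 classes stayed called without them, but they hold much of the fall of neutrophils, which was -9.15 points of percent without them against -26.6. The labels call the tissue of all 7 samples HCC tissue but do not state which part of the liver was taken. As 0 treated samples held 20 or more cells of the tumour-like cluster (2 to 8, against 451 to 2098 in the controls), the tissue taken and the treatment cannot be told apart. An effect of the IL-2/CD25 plasmid on tumour growth, on lymphocytes or on both stays open.

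Camera called glycolysis genes lower in 8 classes, and in 0 of them with an estimated correlation. The camera call stayed after subtraction of free RNA and in thinned libraries in 6 classes. These were CD8 T cells, NK cells and ILC1, monocytes and macrophages, neutrophils, dendritic cells and hepatocytes and tumour cells. Free RNA and unequal summed UMIs therefore do not account for these 6 calls as a whole. Thinning left UMIs per cell unequal, so deeper sequencing of the control cells was not tested. Free RNA may account for the fall in B cells (median log2 change -1.72 as counted, -0.216 after subtraction), CD4 T cells (-0.38 and 0.30), plasmacytoid dendritic cells (-1.55 and -0.03) and T cells of cluster 17 (-1.17 and -0.349), where no camera call stayed. A change between clusters does not account for the fall within cDC1, mature dendritic cells and macrophages of cluster 8. There camera called the list lower in 3 of 3 after subtraction (adjusted p = 0.322 in each with an estimated correlation). Within cluster 8 all 13 complement C1q and Kupffer cell genes rose, so a change of cell type inside that cluster stays open. In NK cells and ILC1 a part played by a change of clusters stays open. Their cluster 26 went from a median of -0.716 as counted to -0.116 after subtraction (quartiles -0.519 and 0.274, camera adjusted p = 0.475). It held 114 of 14046 treated cells of this class (0.81%), grouped with 91.0% of the control cells. Such cells were picked for their likeness to controls, so they cannot speak for the other treated cells. Over the whole class the median after subtraction was -0.913. In CD8 T cells, neutrophils and hepatocytes and tumour cells clusters and groups cannot be told apart, since 0 clusters held 20 or more cells in at least 2 samples of each group, and an effect of the treatment stays open and untested in all 6 classes.

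Other splits of the 7 samples into 3 and 4 were counted for each class. In all 13 classes and clusters only the real split, 1 of 35, gave as many changed genes. This share of 0.0286 is the lowest that 35 splits allow, and it was not adjusted over the 13. Chance is thus unlikely but not excluded, and the splits cannot tell the treatment from other differences between the groups. The real count and the highest of the other splits were 6209 and 0 in CD8 T cells, 292 and 183 in CD4 T cells, 5916 and 0 in NK cells and ILC1, 2039 and 89 in B cells, 5167 and 1038 in monocytes and macrophages, 3778 and 1 in neutrophils, 6028 and 362 in dendritic cells and 4161 and 2815 in hepatocytes and tumour cells. In single clusters they were 1488 and 67 in plasmacytoid dendritic cells, 3035 and 926 in cDC1, 1523 and 305 in mature dendritic cells, 3022 and 1095 in macrophages of cluster 8 and 890 and 4 in T cells of cluster 17. For the number of lists past the threshold, 68, chance stays open, since 2 of 35 splits gave as many. The other splits gave a median of 32 lists and at most 70.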
